A study of Mus musculus with 9 samples.

How the data were processed

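RNA was measured on Affymetrix oligonucleotide arrays in natural killer (NK) cells of mice. Per the labels, the cells were purified by fluorescence-activated sorting from spleens of IL15tg mice, from spleens of NKDxIL15tg mice and from bone marrow of NKDxIL15tg mice. Each of the 3 groups holds 3 biological replicates, and the 9 columns of the deposited table match the 9 labelled samples with 0 columns left over. IL15tg mice carry a transgene for the cytokine IL-15, which NK cells need to survive. NKD mice are a transgenic line with a deficit of mature NK cells, and the insertion of their transgene was reported at the Atf2 gene. The labels state that total RNA was extracted with Trizol and that 150 ng of each sample went through a kit with 2 cycles of amplification from the 3' end before labelling with biotin. Such amplification shortens the product, so that probe sets far from the 3' end of a transcript can read low.

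The authors deposited 1 linear intensity per probe set and array, for 45101 probe sets. How the probes were summarised and how the arrays were scaled is not given in the sources used here, and the raw image data were not used here. The medians of log2 intensity differed by at most 0.20 between arrays, below the 0.3 set as the limit for rescaling, so the values were used as deposited. The 75th percentile differed more, at 167.7 in NKDxIL15tg bone marrow replicate 3 and 130.6 to 140.6 in the other arrays. Scaling to a common 75th percentile was run as an alternative. Intensities below a floor of 16 (4.35% of all values) were set to 16 and all values were transformed to log2. The 64 control probe sets were left out of the tests. Probe sets whose mean log2 intensity over the 9 arrays reached the 40th percentile, 5.58 (an intensity of 47.7), were tested, which left 27022. No pair of arrays shared more than 50% of its values.

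Probe sets were named from the platform annotation. Of all probe sets, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none; the first group covers 18193 genes. Chromosomes come from the mouse reference assembly GRCm38.p6, which was used for gene names and chromosomes only.

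A model of 3 group means was fitted to the log2 intensities of all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with their defaults), and 3 differences were tested 2-sided: NKDxIL15tg spleen against IL15tg spleen, NKDxIL15tg bone marrow against NKDxIL15tg spleen, and NKDxIL15tg bone marrow against IL15tg spleen. The first differs in maturity, as the series' design text names it, and in the NKD genotype together, and the last in organ as well. All 3 groups share 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg over the tested probe sets of a comparison, with a threshold of 0.05. Positive log2 changes are higher in the group named before "against". Errors of log2 changes are standard errors from limma, and errors of intensities are standard deviations (SD) of 3 arrays. An exact test of 3 against 3 arrays cannot give a p below 0.1, so single genes were not tested that way. Detection was tested on simulated data: of 50 genes with an added change, 12% (1.5-fold), 68% (2-fold), 98% (4-fold) and 100% (8-fold) were called in NKDxIL15tg against IL15tg spleen, and 16%, 68%, 94% and 100% in NKDxIL15tg bone marrow against spleen. The simulated noise was independent and had the same spread in all groups. It did not hold a wider spread of the bone marrow group, whose replicate 3 stood apart. The rates for bone marrow may therefore be too high. The limma p-values set each difference against the spread between these samples, pooled over the 3 groups and with bone marrow replicate 3 included.

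The number of arrays limits the precision. The median standard error of a log2 change was 0.15 over the tested probe sets.

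For gene lists, each gene was represented by the brightest of its probe sets with 1 symbol (12925 genes past the filter). Members were counted as risen or fallen after adjustment over all these genes, and again when adjusted over the list alone. Adjusted p-values printed beside single genes are those over all probe sets. Each list of at least 5 tested genes (27 of 28 lists) was compared with all other genes by camera with a preset correlation of 0.01, 2-sided, adjusted over lists. Camera with an estimated correlation and fry, which asks whether the members of a list move on balance in 1 direction and does not compare them with other genes, were run beside it. Of 45 list calls in the 3 comparisons, 5 held with the estimated correlation and 33 with fry.

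The lists were mature NK cell genes, immature NK cell genes, genes associated with type 1 innate lymphoid cells (ILC1), Ly49 receptors, other NK receptors, cytotoxic effectors, NK transcription factors, cytokine receptors and survival, chemokines with homing receptors and integrins, cytokines and the TNF family, cell cycle, interferon-stimulated genes, immediate-early and stress genes, CREB/ATF and AP-1 partners, neighbours of the Atf2 locus, MHC class I and antigen processing, oxidative phosphorylation, cytoplasmic ribosomal proteins, glycolysis, and cholesterol synthesis. Markers of other cells were listed for T cells, B cells, granulocytes and monocytes, macrophages and dendritic cells, erythroid cells, megakaryocytes and platelets, stem and progenitor cells with mast cells and basophils, and stroma with endothelium. Some lists share genes, so their results are not independent. With the mature NK cell list, the chemokine and integrin list shares Itgam, Cx3cr1, S1pr5, Itgal, Itgb2, Ccl3, Ccl4 and Ccl5. The transcription factor list shares Zeb2, Tbx21, Prdm1, Klf2 and Irf8 with it.

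Named genes followed a rule with several parts. It took the 10 genes that rose most and the 10 that fell most among called probe sets with 1 symbol, with a mean in the higher group at or above the median of all probe sets, and with no overlap between the 3 values of each group. It took up to 4 called members of each list, those with the largest change. It took in every case Atf2, Klra1, Itgam, Klrg1, Cd27, Kit, Itgav, Tnfsf10, Gzma, Gzmb, Prf1, Eomes, Tbx21, Il2rb, Klrb1c, Ncr1 and Il15. For a tested list with no called member, up to 2 members are given as values. The groups, tests, filter, lists, rule and all but 1 of the alternatives were chosen before the data were examined. Genes outside the rule are said in the text to have been chosen after their values were seen.

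The replicate numbers were tested as pairs by correlating the departures of same-numbered arrays from their group means. The correlations were 0.163, 0.156 and 0.123 between NKDxIL15tg and IL15tg spleen and 0.379, 0.258 and 0.228 between NKDxIL15tg bone marrow and spleen. They were 0.170, -0.02 and 0.242 between NKDxIL15tg bone marrow and IL15tg spleen. Arrays of different numbers gave -0.370 to 0.267 over all comparisons together. Between NKDxIL15tg bone marrow and spleen alone they gave -0.349 to -0.007, all below the same-numbered arrays. Departures from a group mean cancel within the group, so positive correlations of same-numbered arrays hold those of other arrays down. This gap is therefore partly built in. In the other comparisons the ranges overlapped. The labels name no shared animal or day. A fit with the replicate number as a block was therefore run as an alternative and stands beside the first 2 comparisons.

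Alternatives were no filter, a filter at the 60th percentile, quantile normalization, scaling to a common 75th percentile, a floor of 64, eBayes with trend and robust options, a fit to the 6 arrays of a comparison alone, array weights from limma, 1 probe set per gene, the mean of a gene's probe sets, its next brightest probe set (called the second in the text, tested without the filter), a minimum of 2-fold, the replicate block, and leaving out each array in turn. Where leaving out an array left 2 arrays in a group, the spread was still pooled over all groups. The replicate block without NKDxIL15tg bone marrow replicate 3 was added after seeing the data. Both NKDxIL15tg groups were compared with the same IL15tg arrays, so their shared changes were set beside 100 simulated draws of unchanged groups against shared controls. Plots were drawn with Matplotlib 3.10.9 in Python 3.11.15.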

Results

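RNA levels were measured with 9 Affymetrix arrays in sorted natural killer (NK) cells, the cytotoxic lymphocytes of innate immunity. Each of 3 groups had 3 arrays. They were spleen NK cells of IL15tg mice, which the series' design text calls mature, and spleen and bone marrow NK cells of NKDxIL15tg mice, which it calls immature. Median intensity was 56.6 to 59.1 in 8 arrays and 64.9 in NKDxIL15tg bone marrow replicate 3. This array stood apart in other measures too. Its mean rank correlation with its own group was 0.877, against 0.916 to 0.976 in the other arrays. In it, 2080 probe sets (7.70% of those tested) lay over 2-fold above all 8 other arrays, against at most 6 in any other array. The log2 ratio of the 3' to the 5' probe set of actin, a sign of RNA length, was 0.93 in it and 1.49 to 2.73 in the others. The same ratio for Gapdh did not set it apart (2.33, against 1.62 to 3.21 in the others), but parted the spleen groups without overlap, at 1.99 to 3.21 in IL15tg and 1.62 to 1.87 in NKDxIL15tg. The first principal component (51.6% of the variance) parted IL15tg from NKDxIL15tg arrays, and the second (28.8%) parted this array from the rest. Changes below are log2 changes ± standard error with n = 3 arrays per group, and in every named gene reported as risen or fallen the 3 arrays of one group all lay beyond the 3 of the other.

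NKDxIL15tg spleen against IL15tg spleen set immature NK cells against mature ones within an organ. All immature arrays and no mature array come from NKD mice, so maturity and the NKD genotype cannot be told apart. Of 21 genes of mature NK cells, 10 fell. Itgam, the integrin chain CD11b that marks NK cell maturation, fell by 2.77 ± 0.13, from an intensity of 378 ± 36.3 to 55.7 ± 7.82 (SD, n = 3). Cx3cr1, a chemokine receptor of mature NK cells, fell by 4.66 ± 0.30, and the chemokine gene Ccl3 fell by 4.30 ± 0.29 (2035 to 107). The granzyme Gzmk rose by 3.97 ± 0.09 from 237 ± 11.5 to 3706 ± 145. Of 43 genes of cell division 31 rose, of 20 markers of granulocytes and monocytes 8 rose, and of 16 markers of B cells 5 fell. As lists these passed in camera, with adjusted p = 0.221, 0.480 and 0.480 with an estimated correlation.

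Of 21 genes known to be higher in mature NK cells, 10 fell, 0 rose and 11 did not pass (13 fell when adjusted over the list alone). Among them were Zeb2, a transcription factor of the last steps of maturation (-2.78 ± 0.32, adjusted p = 0.000754), and Tbx21, which encodes T-bet (-1.29 ± 0.25, adjusted p = 0.0113, but 0.0517 without IL15tg replicate 1). A dimmer second probe set of Cx3cr1 gave -0.21 (adjusted p = 0.642). Against all other genes the list was lower in camera, with a mean change of -1.31 (adjusted p = 1.01e-11, and adjusted p = 0.0124 with an estimated correlation). Between the same arrays the granulocyte and monocyte list was at a mean of 1.41 and the erythroid list at 0.67 (adjusted p = 0.480 and 0.156 with an estimated correlation). Klrg1, a receptor of the most mature NK cells, did not pass, at -1.43 ± 0.63 (adjusted p = 0.180, but 0.0461 without NKDxIL15tg bone marrow replicate 3, which enters through the shared spread).

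Genes known to be higher in immature NK cells did not move 1 way: of 20, 3 rose, 4 fell and 13 did not pass (4 rose and 6 fell adjusted over the list alone). Sox4, a transcription factor of lymphoid progenitors, rose by 4.55 ± 0.43, while Il7r, the receptor for interleukin 7, fell by 3.08 ± 0.20, Ltb, a TNF-family ligand, fell by 3.20 ± 0.43 and Il18r1 fell by 2.92 ± 0.41. Kit, the receptor for stem cell factor, fell by 2.19 ± 0.15 (139 to 30.6), while its second probe set gave -0.21 (adjusted p = 0.514). Cd27 (0.04, adjusted p = 0.957), Itgav (-0.27, adjusted p = 0.551) and Tnfsf10, which encodes TRAIL (-0.05, adjusted p = 0.946), did not pass, although a second probe set of Tnfsf10 gave -0.86 (adjusted p = 0.0226). The list as a whole did not pass (adjusted p = 0.0703), but did with quantile normalization (0.0331), with scaling to the 75th percentile (0.0330), with the mean of probe sets (0.0480), without NKDxIL15tg spleen replicate 2 (0.0384) and without bone marrow replicate 3 (0.0451). Of 15 genes associated with ILC1, innate relatives of NK cells, 2 rose and 5 fell (3 and 6 adjusted over the list alone). The list was lower (adjusted p = 0.0166, and adjusted p = 0.156 with an estimated correlation). Ikzf2, which encodes Helios, fell by 2.40 ± 0.28, and Inpp4b, a lipid phosphatase, rose by 2.68 ± 0.24, with 0.10 (adjusted p = 0.792) in its second probe set. Il7r, Ltb, Tnfsf10, Rora and Cxcr3 stand in both of these lists.

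Of 22 receptors by which NK cells recognise targets, 9 fell, 1 rose and 12 did not pass (10 fell and 1 rose adjusted over the list alone). Klrc1 (NKG2A, -3.58 ± 0.41), Klrk1 (NKG2D, -3.09 ± 0.50) and Klrd1 (CD94, -2.40 ± 0.46) fell, and Slamf6 (Ly108), a receptor of the 2B4 family, rose by 2.73 ± 0.16. The list was lower (adjusted p = 0.00155, and adjusted p = 0.160 with an estimated correlation). Ncr1 (NKp46) did not pass at -0.60 ± 0.21 (adjusted p = 0.0890, but 0.0279 with quantile normalization and 0.0256 without bone marrow replicate 3). Ly49 receptors are near-identical paralogs, and their probe sets can cross-react: 7 had a probe set of their own and 3 were tested. Of these, Klra5 fell by 1.96 ± 0.37, Klra8 (Ly49H) fell by 2.31 ± 0.49 (adjusted p = 0.0153, but 0.0513 to 0.0585 without any one of IL15tg replicates 1, 2 and 3), and Klra7 did not pass (0.12, adjusted p = 0.580). Klra1 lay under the filter with mean intensities of 12.8, 10.3 and 12.9 in the 3 groups, and Klrb1c, which encodes NK1.1, has no probe set of its own and was not analysed here.

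Cytotoxic effectors split. Of 22, 5 rose and 1 fell (5 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.941), with a median of -0.05, a mean of 0.10 and a test pointing down. Beside Gzmk, Gzmm rose by 1.20 ± 0.17, and Serpinb9b, a granzyme inhibitor, fell by 2.30 ± 0.19. Gzma (-0.13, adjusted p = 0.523), Gzmb (-0.24, adjusted p = 0.753) and Prf1, which encodes perforin (-0.48, adjusted p = 0.0996), did not pass. Of 38 transcription factors of NK cell development, 5 rose and 9 fell (5 and 11 adjusted over the list alone). The list was lower (adjusted p = 0.0225, and adjusted p = 0.504 with an estimated correlation). Maf, a factor of cytokine production in lymphocytes, rose by 1.80 ± 0.12, and Eomes, which NK cells need to mature, did not pass (0.35 ± 0.13, adjusted p = 0.122).

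Cytokine receptors and survival genes included 3 of 27 that rose and 7 that fell (5 and 10 adjusted over the list alone). Il18rap, the partner chain of Il18r1, fell by 1.59 ± 0.24, and Il2rb, the chain through which NK cells sense IL-15, did not pass (0.37, adjusted p = 0.404). The list was lower (adjusted p = 0.0359, and adjusted p = 0.480 with an estimated correlation), but not with the replicate block (0.0740) or without IL15tg replicate 1 (0.0624), IL15tg replicate 2 (0.0775) or NKDxIL15tg spleen replicate 3 (0.0838). Of 30 chemokines, homing receptors and integrins, 4 rose and 7 fell (5 and 10 adjusted over the list alone; adjusted p = 5.02e-05, and adjusted p = 0.156 with an estimated correlation). Itgax, the integrin chain CD11c, fell by 4.81 ± 0.17, from 1703 to 60.8. Among 23 cytokine and TNF family genes, 2 rose and 4 fell (3 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.198). Ifng, the main cytokine of NK cells, fell by 2.16 ± 0.23 (2838 to 649), and Il2 rose by 2.20 ± 0.22 (40.5 to 184). Il15 did not pass (0.42, adjusted p = 0.518).

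Cell cycle genes rose in 31 of 43 cases, 0 fell and 12 did not pass (34 rose adjusted over the list alone). Ccna2 (cyclin A2) rose by 1.82 ± 0.22, with 1.64 (adjusted p = 0.0538) in its second probe set, and Cdk1, the kinase of mitotic entry, by 1.59 ± 0.29, whereas Nusap1 rose by 1.81 ± 0.29 in one probe set and gave 0.19 (adjusted p = 0.623) in another. The list was higher, with a mean of 0.91 (adjusted p = 4.32e-15, and adjusted p = 0.221 with an estimated correlation), beside granulocyte and monocyte genes at 1.41 and erythroid genes at 0.67. Of 33 immediate-early and stress genes, which respond within minutes to stimulation and to cell handling, 11 fell and 0 rose (17 fell adjusted over the list alone). Fos (-2.72 ± 0.48), Klf4 (-1.67 ± 0.22) and Dusp2 (-1.44 ± 0.19) fell, and the list was lower (adjusted p = 4.69e-11, and adjusted p = 0.0309 with an estimated correlation).

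Genes of MHC class I and antigen processing rose in 6 of 16 cases and 0 fell (10 rose adjusted over the list alone). They include Psmb9 (1.07 ± 0.16) and Psmb8 (1.20 ± 0.15, with 0.86 and adjusted p = 0.0779 in its second probe set), subunits of the immunoproteasome. The list was higher (adjusted p = 7.57e-05, and adjusted p = 0.231 with an estimated correlation). Of 72 oxidative phosphorylation genes, 10 rose and 1 fell (14 and 2 adjusted over the list alone), with Ndufc2 of complex I at 0.79 ± 0.10 and Cox6a2 of complex IV at -0.85 ± 0.10. Its adjusted p was 0.00324 (0.0631 without IL15tg replicate 1, and adjusted p = 0.504 with an estimated correlation). Of 45 ribosomal protein genes, 5 rose and 0 fell (5 adjusted over the list alone), with the list at adjusted p = 0.00324 and adjusted p = 0.504 with an estimated correlation. Glycolysis genes rose in 3 of 20 cases (3 adjusted over the list alone), among them Hk2 (1.00 ± 0.16), and the list did not pass (adjusted p = 0.0817, but 0.0466 without a filter and 0.00999 without NKDxIL15tg spleen replicate 3). The list lacks Gapdh, Gpi1 and Eno1, which had no probe set of their own outside the controls. The 3 control probe sets of Gapdh were higher in the 6 NKDxIL15tg than in the 3 IL15tg arrays, by 0.92 to 1.58. Of 20 cholesterol synthesis genes 1 rose, Mvd (0.90 ± 0.22, adjusted p = 0.0266, but 0.0542 to 0.0973 without IL15tg replicates 1, 2 or 3 or NKDxIL15tg spleen replicates 1 or 2 and 0.0762 with a floor of 64), with 0 adjusted over the list alone. The list did not pass (adjusted p = 0.0534). It passed with the replicate block (0.0351), without a filter (0.0319), with the mean of probe sets (0.0402), and without IL15tg replicate 3 (0.0387), NKDxIL15tg spleen replicate 1 (0.0299) or 3 (0.0380) or bone marrow replicate 3 (0.0264). Of 27 interferon-stimulated genes 2 rose, Rsad2 (1.19 ± 0.23, with 1.11 and adjusted p = 0.169 in its second probe set) and Isg20 (1.00 ± 0.16), and 4 adjusted over the list alone (list adjusted p = 0.941, median -0.03, mean 0.09).

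Atf2, at which the NKD transgene insertion was reported, was measured at 661 ± 65.7 in IL15tg spleen, 762 ± 154 in NKDxIL15tg spleen and 732 ± 240 in NKDxIL15tg bone marrow, and did not pass (0.19 ± 0.23, adjusted p = 0.689). Where its probe set lies relative to the insertion is not given in the sources used here. Of 15 genes of its family and partners, Crem rose by 1.11 ± 0.12 and Atf6 fell by 0.87 ± 0.14 (1 and 2 adjusted over the list alone; list adjusted p = 0.267). Of 14 neighbours of the Atf2 locus, Mtx2 rose by 1.05 ± 0.17 and Gpr155 fell by 1.12 ± 0.16 (1 and 1 adjusted over the list alone; list adjusted p = 0.807).

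Markers of granulocytes and monocytes rose in 8 of 20 cases and 0 fell (9 adjusted over the list alone). S100a8, a calcium-binding protein abundant in neutrophils, rose by 3.55 ± 0.47 from 148 to 1806, and Camp, an antimicrobial peptide of neutrophil granules, by 3.17 ± 0.47. The list was higher (adjusted p = 7.07e-05, and adjusted p = 0.480 with an estimated correlation). Of 14 erythroid genes 5 rose and 0 fell (7 adjusted over the list alone; adjusted p = 0.000145, and adjusted p = 0.156 with an estimated correlation), with the carbonic anhydrase Car2 up by 2.32 ± 0.14 and Alas2, of haem synthesis, by 1.98 ± 0.21. B cell genes fell in 5 of 16 cases (5 adjusted over the list alone; adjusted p = 0.0152, and adjusted p = 0.480 with an estimated correlation), with Cd79b at -2.07 ± 0.27 and Ms4a1, which encodes CD20, at -1.61 ± 0.24. Of 20 macrophage and dendritic cell genes 6 fell (6 fell and 1 rose adjusted over the list alone). They were Itgax, which NK cells also express, and genes of MHC class II presentation or dendritic cells such as H2-Aa (-1.28 ± 0.25) and H2-Eb1 (-1.18 ± 0.20). That list was lower (adjusted p = 0.0244, and adjusted p = 0.480 with an estimated correlation), but not without a filter (0.112) or without IL15tg replicate 2 (0.0727), NKDxIL15tg spleen replicate 1 (0.0607) or 2 (0.0853). Of 12 T cell genes 2 rose (2 adjusted over the list alone; list adjusted p = 0.244), including the costimulatory receptor Cd28 (2.10 ± 0.16). Of 5 megakaryocyte genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; list adjusted p = 0.902, median -0.01, mean 0.00). No member passed among 12 stem, mast cell and basophil genes (list adjusted p = 0.878, median -0.02, mean 0.04) or 7 stromal genes (list adjusted p = 0.902).

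Several of the genes that rose most lay near the floor in IL15tg spleen. Cpe, which encodes carboxypeptidase E, rose by 6.10 ± 0.22 from 14.5 to 1151, Coch, an extracellular matrix protein, by 5.49 ± 0.12 from 54.7 to 2466, the homeobox gene Dlx1 by 5.36 ± 0.17 and the T-box gene Tbx18 by 5.23 ± 0.18. Where the lower group lay under the floor of 16, as for Cpe and Tbx18, the change depends on the floor. The remaining genes of the top 10 were Cntnap2, Dmrta2, Erc2, Ptprg, Ccn3 and Epha3, with changes of 4.92 to 5.29, and a second probe set of Ptprg gave 0.33 (adjusted p = 0.0775). Falling genes in the top 10 not yet named were AI504432 (-4.39), Slc9a9 (-3.44), Sgk1 (-3.27) and Kcnj8 (-3.16).

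The Gapdh ratio of 3' to 5' signal was lower in all 3 NKDxIL15tg than in all 3 IL15tg spleen arrays (1.62 to 1.87 against 1.99 to 3.21), while the actin ratio overlapped (1.54 to 2.03 against 1.80 to 2.73). In limma, 3725 of 27022 probe sets (13.8%) differed between NKDxIL15tg and IL15tg spleen. Of these 1823 were higher and 1902 lower, and 1249 changed at least 2-fold (631 higher, 618 lower). The groups did not overlap in 38.1% of probe sets, against a chance share of 10%. With the replicate block the count was 3789. The count was 1809, 1812 and 2070 without IL15tg replicates 1, 2 and 3 and 2112 without NKDxIL15tg spleen replicate 2, and 5685 with array weights. Without bone marrow replicate 3, which enters through the shared spread, it was 5483 and held all 3725. Of 93 named genes that passed, 72 passed in every fit without 1 array, and 27 of 45 with a second probe set passed there too.

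**Figure D1:**
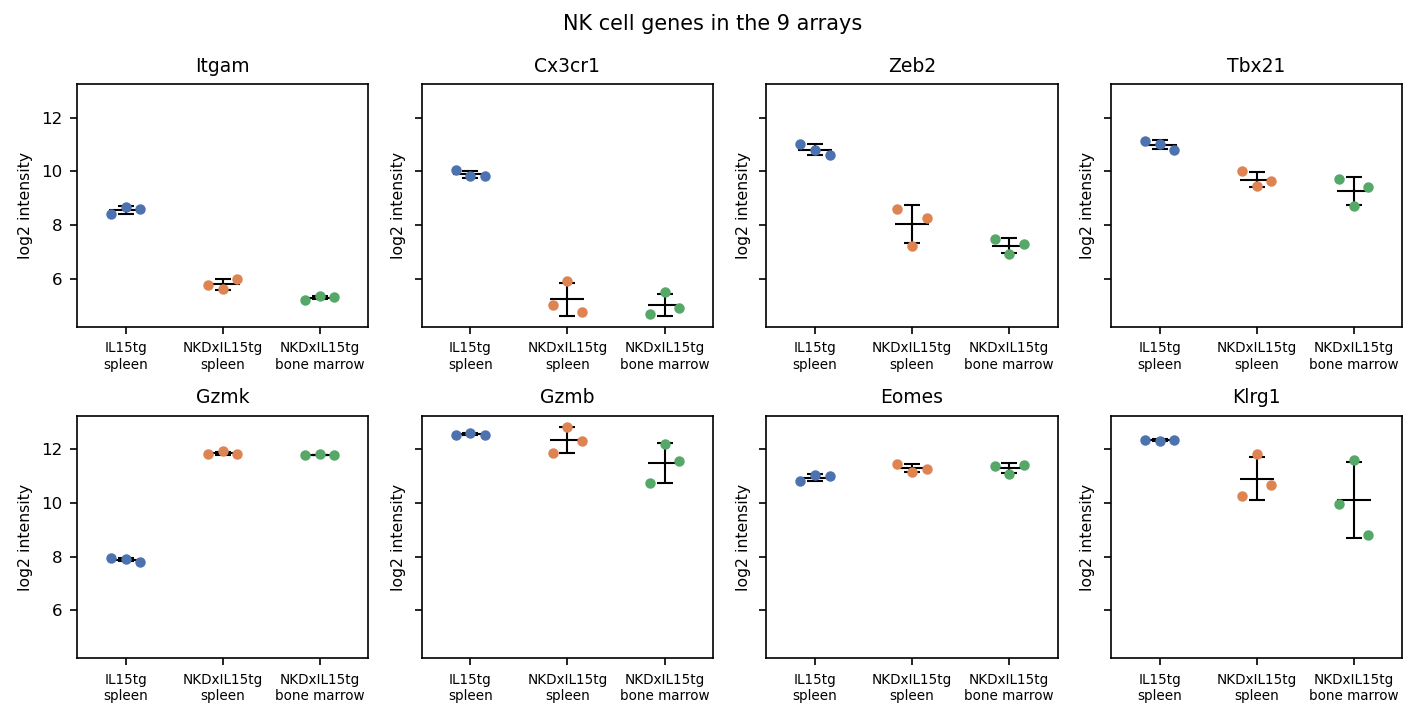
Log2 intensity (y axis) of 8 NK cell genes in the 3 groups, with a dot for each array, a dash for the group mean and bars of 1 SD. Itgam, Cx3cr1, Zeb2 and Tbx21 lie lower in both NKDxIL15tg groups (Itgam at 378 in IL15tg spleen and 55.7 and 39.5 in NKDxIL15tg spleen and bone marrow), Gzmk lies higher, and Klrg1 is spread widely within the NKDxIL15tg groups.

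NKDxIL15tg bone marrow against NKDxIL15tg spleen asked how the cells sorted as NK cells differ between 2 organs. No value here measures the purity of the sort. Ctsg (3.47 ± 0.39, 61.2 to 721), Prtn3 (3.25 ± 0.36, 67.1 to 694) and Mpo (2.71 ± 0.30, 161 to 1126), which encode proteases and the peroxidase of neutrophil granules, rose in bone marrow. Jchain, which joins secreted antibodies (-4.38 ± 0.39, 469 to 23.9), Ms4a1 (-2.94 ± 0.24), the immunoglobulin light chain gene Igkv8-30 (-2.51 ± 0.24), the transcription cofactor Pou2af1 (-2.27 ± 0.23) and the complement receptor Cr2 (-1.67 ± 0.17) fell. Matn2, a matrix protein, fell by 1.40 ± 0.11 and Macir fell by 0.98 ± 0.11. Adjusted p lay between 0.00506 and 0.0200 for these 10 genes, and none of them passed without NKDxIL15tg spleen replicate 1 (0.0691 to 0.115). Ctsg, Prtn3 and Mpo also did not pass without spleen replicate 2 or 3 (0.0779 to 0.117) or bone marrow replicate 2 (0.0638 to 0.0982), nor did Pou2af1 and Cr2 without any 1 of these or bone marrow replicate 1 (up to 0.113). The same held for Jchain without spleen replicate 3 (0.0598), for Igkv8-30 without bone marrow replicate 2 (0.0638) and for Macir without spleen replicate 3 (0.147) or bone marrow replicate 1 (0.0578) or 2 (0.116).

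No member of the lists of NK cell receptors, effectors or transcription factors passed on its own. Of 20 granulocyte and monocyte genes 3 rose (17 adjusted over the list alone), with a list mean of 1.95 (adjusted p = 4.76e-18, and adjusted p = 0.180 with an estimated correlation). The mean log2 level of this list was 6.99, 7.36 and 7.83 in the 3 NKDxIL15tg spleen arrays and 8.57, 9.34 and 10.11 in the 3 bone marrow arrays, with the divergent array last. Of 16 B cell genes 4 fell (6 fell and 1 rose adjusted over the list alone; adjusted p = 4.15e-05, and adjusted p = 0.180 with an estimated correlation). Of 20 macrophage and dendritic cell genes 0 passed (7 fell adjusted over the list alone; adjusted p = 1.01e-05, and adjusted p = 0.180 with an estimated correlation), with Cd74, of MHC class II, at -1.13 (adjusted p = 0.254).

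Mature NK cell genes were lower in bone marrow as a list, with a mean of -0.43 (adjusted p = 1.21e-08, and adjusted p = 0.0304 with an estimated correlation), while 0 of 21 passed singly (4 fell adjusted over the list alone). Their largest changes were S1pr5, the receptor by which NK cells leave bone marrow (-1.91, adjusted p = 0.178, but 0.0250 without NKDxIL15tg spleen replicate 2), and Gzmb (-0.84, adjusted p = 0.469). Cell cycle genes were higher as a list, with a mean of 0.56 (adjusted p = 2e-14, and adjusted p = 0.191 with an estimated correlation), and 0 of 43 passed singly (14 rose adjusted over the list alone), with Cenpf at 0.91 (adjusted p = 0.399). Between the same arrays the granulocyte and monocyte list rose by a mean of 1.95 (adjusted p = 0.180 with an estimated correlation) and the B cell list was at -0.72 (adjusted p = 0.180). Cytotoxic effectors (mean -0.17) and immediate-early genes (mean -0.24) were lower as lists, both with adjusted p = 0.00115 and adjusted p = 0.180 with an estimated correlation, with 0 of 22 and 0 of 33 passing (0 and 0 adjusted over the list alone). Fos was at -1.35 (adjusted p = 0.455). Oxidative phosphorylation genes were higher as a list (mean 0.19, adjusted p = 1.44e-05, and adjusted p = 0.348 with an estimated correlation) with 0 of 72 passing (0 adjusted over the list alone).

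A further 5 lists passed with small mean changes and no member passing singly. Ribosomal protein genes stood at 0.11 (adjusted p = 0.0101, and adjusted p = 0.489 with an estimated correlation; 0 adjusted over the list alone), but at adjusted p = 0.118 without NKDxIL15tg spleen replicate 1, 0.110 without bone marrow replicate 2, 0.150 with quantile normalization and 0.239 with scaling to the 75th percentile. Chemokines and homing receptors stood at -0.09 (adjusted p = 0.0229, and adjusted p = 0.320 with an estimated correlation; 5 fell adjusted over the list alone), but at 0.162 without bone marrow replicate 2 and 0.0512 with quantile normalization. Transcription factors stood at -0.08 (adjusted p = 0.0248, and adjusted p = 0.465 with an estimated correlation; 1 fell adjusted over the list alone), but at 0.232 (mean 0.004) and 0.0558 without NKDxIL15tg spleen replicates 1 and 3, 0.376 (mean 0.032) without bone marrow replicate 2, 0.0653 with quantile normalization and 0.0583 with scaling to the 75th percentile. Klf12 had the largest change among these factors (-1.27, adjusted p = 0.0898). Interferon-stimulated genes stood at -0.12 (adjusted p = 0.0248, and adjusted p = 0.180 with an estimated correlation; 1 fell adjusted over the list alone), but at 0.0646 and 0.136 without NKDxIL15tg spleen replicates 2 and 3 and 0.110 and 0.0585 without bone marrow replicates 1 and 3. CREB/ATF partners stood at -0.10 (adjusted p = 0.0322, and adjusted p = 0.180 with an estimated correlation; 0 adjusted over the list alone), but at 0.162 without NKDxIL15tg spleen replicate 1, 0.110 without bone marrow replicate 2, 0.0744 with quantile normalization and 0.327 with the mean of probe sets.

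Other NK receptors did not pass as a list (adjusted p = 0.0552), but did with the replicate block (0.0409), with the mean of probe sets (0.0246) and without bone marrow replicate 3 (0.00469) or NKDxIL15tg spleen replicate 1 (0.0441) or 2 (0.0242). Cytokine receptors did not pass (adjusted p = 0.0735), but did without a filter (0.0407), with the mean of probe sets (0.0471) and without bone marrow replicate 3 (0.0226) or NKDxIL15tg spleen replicate 2 (0.0401) or 3 (0.0367), and Il18r1 was at -1.73 (adjusted p = 0.332, but 0.0250 without NKDxIL15tg spleen replicate 2). No call was made for immature NK cell genes (adjusted p = 0.804), ILC1 genes (0.156), cytokines and the TNF family (0.975, median 0.17, mean 0.08, test pointing down), neighbours of Atf2 (0.446, median 0.02, test pointing down), MHC class I (0.907, median 0.03, test pointing down), glycolysis (0.325) or cholesterol synthesis (0.0828). Nor was one made for T cells (0.610), erythroid cells (0.123), megakaryocytes (0.351), stem and mast cells (0.238) or stroma (0.804, median -0.03, mean 0.09). Of these, 5 lists passed in other settings. ILC1 genes were lower without NKDxIL15tg spleen replicate 1 (0.0483), and glycolysis was higher without NKDxIL15tg spleen replicate 2 (0.0242). Cholesterol synthesis was lower without a filter (0.0493) and without NKDxIL15tg spleen replicate 1 (0.0255) or 3 (0.0402) or bone marrow replicate 2 (0.0277). Erythroid genes were lower with the mean of probe sets (0.0375) and without NKDxIL15tg spleen replicate 1 (0.0375) or bone marrow replicate 3 (0.0313), and stem and mast cell genes were higher without a filter (0.0493). The 3 Ly49 receptors did not pass. Itgam (-0.49), Klrg1 (-0.79), Tbx21 (-0.42), Eomes (0.01), Kit (0.13), Cd27 (0.25), Ncr1 (0.06), Il2rb (-0.34), Prf1 (-0.39), Gzma (-0.21), Itgav (0.15), Tnfsf10 (0.24), Il15 (-0.16) and Atf2 (-0.09) had adjusted p between 0.358 and 0.987.

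In limma, 14 of 27022 probe sets (0.0518%) differed between NKDxIL15tg bone marrow and spleen, 3 higher and 11 lower, and 2816 had an unadjusted p under 0.05. The groups did not overlap in 16.1% of probe sets, against a chance share of 10%. With the replicate block the count was 23, with Macir no longer passing (0.0558), as with quantile normalization (0.0600). It was 2 without a filter. With a floor of 64 it was 4, of which 2 were among the 14, and of the 10 named genes only Matn2 passed, with Cr2 at -0.035, Pou2af1 at -0.27 and Ms4a1 at -1.13 (-1.67, -2.27 and -2.94 with the floor of 16). Without NKDxIL15tg spleen replicate 1 the count was 1, and it was 4 without NKDxIL15tg spleen replicate 3 and 4 without bone marrow replicate 2. Second probe sets of Matn2 (-1.50) and Macir (-0.96) did not pass without the filter. That of Ms4a1 (-2.50) passed with the filter and not without it (adjusted p = 0.113).

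**Figure D2:**
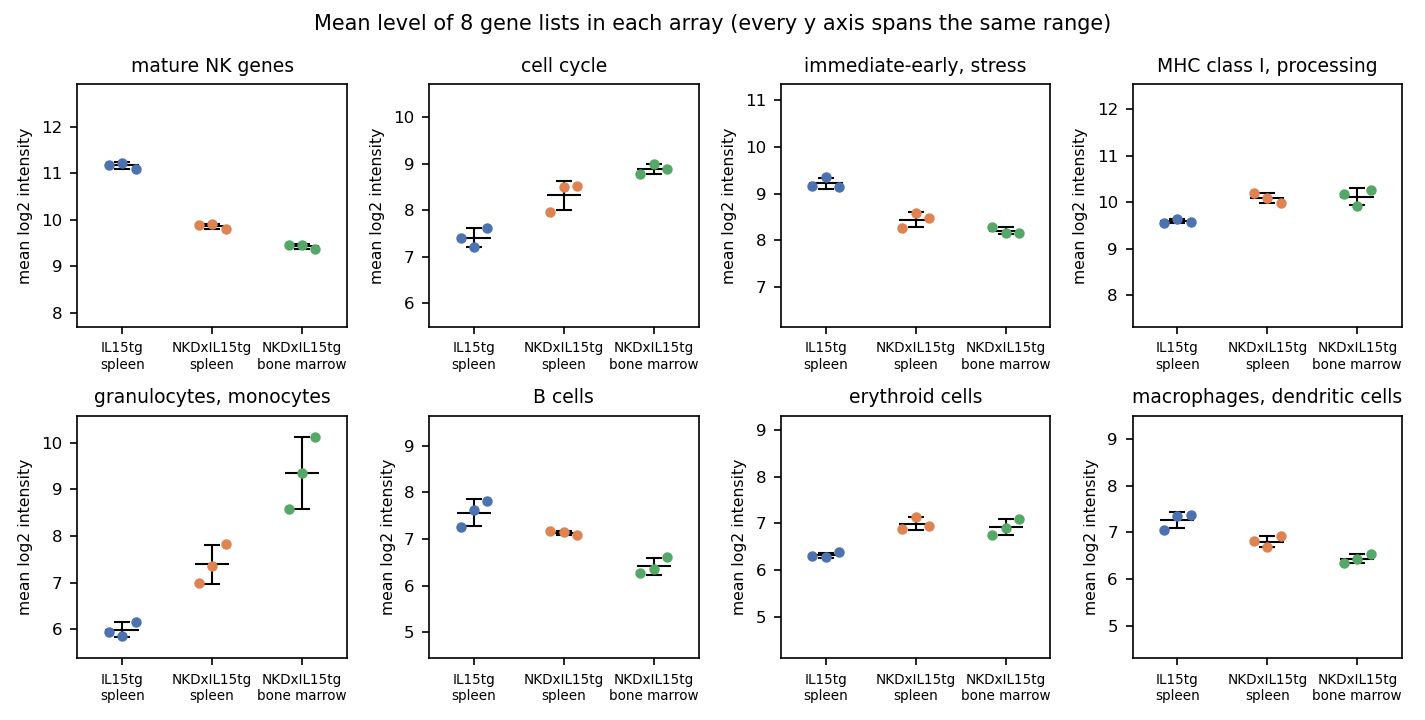
Mean log2 intensity per array (y axis, every panel spanning the same range) of 8 gene lists in the 3 groups, with a dot for each array, a dash for the group mean and bars of 1 SD. Granulocyte and monocyte genes go from 5.86 to 6.16 in IL15tg spleen through 6.99 to 7.83 in NKDxIL15tg spleen to 8.57 to 10.11 in NKDxIL15tg bone marrow, and mature NK cell genes go from 11.09 to 11.23 in IL15tg spleen to 9.37 to 9.46 in NKDxIL15tg bone marrow.

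NKDxIL15tg bone marrow against IL15tg spleen set the immature cells of one organ against the mature cells of another, so organ, maturity and genotype differ together. Of 21 mature NK cell genes 15 fell and 0 rose (19 fell adjusted over the list alone), with a mean of -1.74 (adjusted p = 2.57e-17, and adjusted p = 0.00411 with an estimated correlation). S1pr5 fell by 3.92 ± 0.32 (2237 to 150), and so did Zeb2 (-3.58 ± 0.32), Itgam (-3.26 ± 0.13) and Tbx21 (-1.71 ± 0.25). Of 43 cell cycle genes 38 rose and 0 fell (39 adjusted over the list alone), with a mean of 1.47 (adjusted p = 9.73e-19, and adjusted p = 0.153 with an estimated correlation), Cdk1 at 2.36 ± 0.29 and Kif11, a mitotic motor, at 2.35 ± 0.32. Granulocyte and monocyte genes rose in 17 of 20 cases and 0 fell (18 adjusted over the list alone), with a mean of 3.35 (adjusted p = 1.67e-11, and adjusted p = 0.190 with an estimated correlation) and Camp, S100a8, Ngp and Chil3 at 5.96 ± 0.47, 5.26 ± 0.47, 5.16 ± 0.36 and 5.11 ± 0.52.

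Immature NK cell genes again went both ways, with 3 of 20 risen and 5 fallen (3 and 5 adjusted over the list alone; list adjusted p = 0.214, median 0.08, mean -0.31): Sox4 rose by 4.45 ± 0.43 and Il18r1 fell by 4.65 ± 0.41. Of 15 ILC1 genes 3 rose and 6 fell (3 and 7 adjusted over the list alone; adjusted p = 0.00468, and adjusted p = 0.134 with an estimated correlation). Of 22 other NK receptors 1 rose, Slamf6 (3.39 ± 0.16), and 10 fell (3 and 11 adjusted over the list alone; adjusted p = 0.00012, and adjusted p = 0.134 with an estimated correlation), with Klrc1 at -4.55 ± 0.41 and Klrk1 at -3.10 ± 0.50. Of the 3 Ly49 receptors Klra8 (-2.30 ± 0.49) and Klra5 (-2.17 ± 0.37) fell. Of 22 cytotoxic effectors 5 rose and 4 fell (5 and 7 adjusted over the list alone; list adjusted p = 0.121, but 0.0449 with the mean of probe sets). Gzmk rose by 3.90 ± 0.09, and Prf1 fell by 0.87 ± 0.17, with 0.11 (adjusted p = 0.684) in its second probe set. Klrg1 was at -2.22 ± 0.63 (adjusted p = 0.0363), but at 0.105, 0.0944 and 0.0926 without IL15tg replicates 1, 2 and 3, at 0.0806 without bone marrow replicate 1 and at 0.0829 with a floor of 64. Kit fell by 2.06 ± 0.15, with -0.07 in its second probe set. Gzma (-0.34, adjusted p = 0.0542) and Gzmb (-1.08, adjusted p = 0.0566) did not pass, but had 0.0345 and 0.0193 without bone marrow replicate 2. Gzma also passed with a floor of 64 (0.0277), and Gzmb with quantile normalization (0.0307), scaling to the 75th percentile (0.0358) and the replicate block (0.0192). Ncr1 (-0.55, adjusted p = 0.0907) had 0.0151 without bone marrow replicate 3, 0.0222 with quantile normalization and 0.0438 with scaling to the 75th percentile. Eomes (0.35), Cd27 (0.28), Il2rb (0.03), Itgav (-0.13), Tnfsf10 (0.19), Il15 (0.26) and Atf2 (0.10) had adjusted p between 0.0886 and 0.941.

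Transcription factors rose in 5 and fell in 13 of 38 cases (7 and 15 adjusted over the list alone; adjusted p = 0.00468, and adjusted p = 0.386 with an estimated correlation). Cytokine receptors rose in 2 and fell in 7 of 27 cases (3 and 9 adjusted over the list alone; adjusted p = 0.00763, and adjusted p = 0.280 with an estimated correlation). Chemokines and homing receptors rose in 5 and fell in 10 of 30 cases (5 and 15 adjusted over the list alone; adjusted p = 2.56e-05, and adjusted p = 0.144 with an estimated correlation), with Itgax at -5.04 ± 0.17. Of 23 cytokine genes 2 rose and 5 fell (2 and 5 adjusted over the list alone; list adjusted p = 0.447, median 0.19, mean -0.08), with Ifng at -3.32 ± 0.23. Immediate-early and stress genes fell in 19 of 33 cases (21 adjusted over the list alone; adjusted p = 2.17e-12, and adjusted p = 0.0229 with an estimated correlation), with Fos at -4.07 ± 0.48 and the heat shock gene Hspa1b at -3.09 ± 0.51. MHC class I genes rose in 5 of 16 cases (7 adjusted over the list alone; adjusted p = 0.00127, and adjusted p = 0.279 with an estimated correlation).

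Oxidative phosphorylation genes rose in 28 and fell in 2 of 72 cases (35 and 2 adjusted over the list alone; adjusted p = 2.93e-06, and adjusted p = 0.280 with an estimated correlation), with Ndufs8 at 0.87 ± 0.13. Ribosomal protein genes rose in 12 of 45 cases (17 adjusted over the list alone; adjusted p = 0.00012, and adjusted p = 0.386 with an estimated correlation). Glycolysis genes rose in 5 and fell in 2 of 20 cases (8 and 2 adjusted over the list alone; adjusted p = 0.0355, and adjusted p = 0.428 with an estimated correlation), but the list did not pass without IL15tg replicate 3 (0.0551), bone marrow replicate 1 (0.0658) or 2 (0.0526) or with the mean of probe sets (0.0893). CREB/ATF partners included 1 of 15 risen and 2 fallen (1 and 3 adjusted over the list alone; adjusted p = 0.0374, and adjusted p = 0.190 with an estimated correlation). That list had 0.0551 and 0.0528 without IL15tg replicates 1 and 3, 0.0526 and 0.0539 without bone marrow replicates 2 and 3, 0.0506 without a filter and 0.127 with the mean of probe sets. No call was made for neighbours of Atf2 (0.488, 1 risen and 1 fallen of 14, median 0.08, test pointing down), interferon-stimulated genes (0.246, 1 risen and 1 fallen of 27) or cholesterol synthesis (0.488, 0 risen and 1 fallen of 20).

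B cell genes fell in 7 and rose in 1 of 16 cases (8 and 2 adjusted over the list alone; adjusted p = 0.00012, and adjusted p = 0.190 with an estimated correlation), with Ms4a1 at -4.55 ± 0.24. Macrophage and dendritic cell genes fell in 7 of 20 cases (10 adjusted over the list alone; adjusted p = 1.58e-05, and adjusted p = 0.146 with an estimated correlation), with H2-Aa at -2.25 ± 0.25. Erythroid genes rose in 5 of 14 cases (6 adjusted over the list alone; adjusted p = 0.00518, and adjusted p = 0.190 with an estimated correlation), with Car2 at 2.07 ± 0.14. T cell genes included 2 of 12 risen and 1 fallen (3 and 1 adjusted over the list alone; list adjusted p = 0.172), with Cd28 at 1.88 ± 0.16. Stem, mast cell and basophil genes (1 risen and 1 fallen of 12, list adjusted p = 0.377), megakaryocyte genes (0 of 5, 0.734) and stromal genes (0 of 7, 0.915, median -0.06, mean 0.19) did not pass as lists.

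In limma, 5764 of 27022 probe sets (21.3%) differed between NKDxIL15tg bone marrow and IL15tg spleen, 2646 higher and 3118 lower, with 1769 changed at least 2-fold (762 higher, 1007 lower). The groups did not overlap in 42.9% of probe sets, against a chance share of 10%. The count was 3089 without IL15tg replicate 1 and 3480 without IL15tg replicate 2. Without bone marrow replicate 3 it was 6342, of which 5118 were among the 5764. Of 92 named genes that passed, 80 passed in every fit without 1 array, and 30 of 48 with a second probe set passed there too.

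Both NKDxIL15tg groups differed from IL15tg spleen in 3166 shared probe sets. Of these 1446 were higher in both, among them Coch, Dlx1, Tbx18 and Gzmk, 1720 were lower in both, among them Itgax, Cx3cr1, Ccl3 and Klrc1, and 0 went opposite ways. Independent lists would share 178 higher, 219 lower and 397 opposite. The log2 changes of the 2 comparisons correlated at 0.850 across probe sets, which are not independent replicates. Simulated unchanged groups set against shared controls gave 0.501. Their 0 shared calls cannot be set against the overlap, since few or no calls are made in unchanged groups. The simulated arrays were independent, while the departures of same-numbered NKDxIL15tg bone marrow and spleen arrays correlated at 0.379, 0.258 and 0.228. The covariance of the changes was 0.27, against 0.02 in the simulation. The 3 shared IL15tg arrays cannot be split, so part of the excess can come from them. Without IL15tg replicates 1, 2 and 3 the shared count was 1562, 1631 and 1874, and without NKDxIL15tg spleen replicate 2 it was 1980. Array weights gave 4818.

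**Figure D3:**
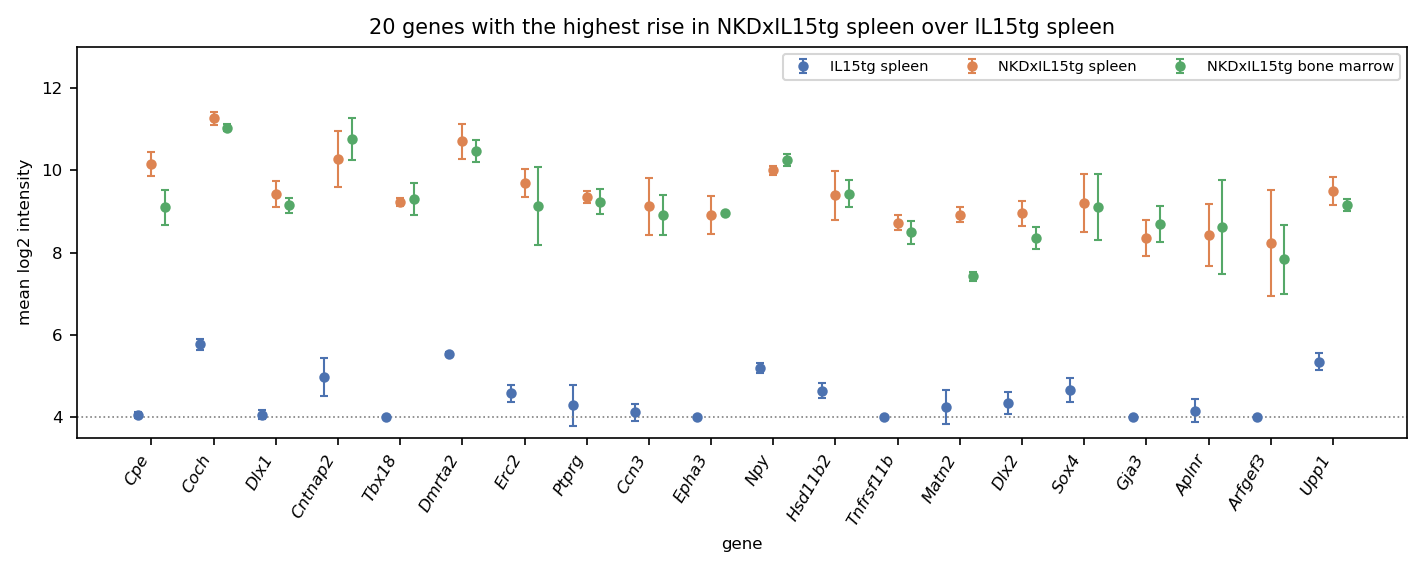
Mean log2 intensity (y axis) of the 20 genes with the highest rise from IL15tg to NKDxIL15tg spleen, in the 3 groups, with bars of 1 SD of 3 arrays and a dotted line at the floor (an intensity of 16, log2 of 4). Each gene lies high in both NKDxIL15tg groups, as Coch does at 2466 and 2108 against 54.7, and many lie near the floor in IL15tg spleen.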

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

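Of the tests in this part, those of the control probe sets, of the organ difference of the strongly risen genes, of other genes of like rise and of their share on chromosome 2, as well as the choice of all other probe sets and the count of genes in the test of faulty probe sets, were chosen after the result was seen. Groups of 3 arrays are too small to test single arrays as extreme values.

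Probe sets that differed between bone marrow and spleen of NKDxIL15tg mice stood out because the organs differed under the same genotype. Higher in bone marrow were Ctsg (3.47), Prtn3 (3.25) and Mpo (2.71). Lower were Macir (-0.98), Matn2 (-1.40), Cr2 (-1.67), Pou2af1 (-2.27), Igkv8-30 (-2.51), both probe sets of Ms4a1 (-2.50 and -2.94), Jchain (-4.38) and 3 probe sets without a gene symbol (-2.40, -3.23 and -3.96). Ctsg, Prtn3 and Mpo are in the granulocyte and monocyte list, and Jchain, Ms4a1, Pou2af1 and Cr2 are in the B cell list. Whether NK cells or other cells in the sort held this RNA was not tested. None of the 10 named genes passed in every fit without 1 array. Without a filter 2 probe sets were called, and with a floor of 64 only Matn2 of the 10 genes was, with Cr2 at -0.035, Pou2af1 at -0.27 and Ms4a1 at -1.13. As lists, granulocyte and monocyte genes (mean 1.95), cell cycle (0.56), oxidative phosphorylation (0.19) and ribosomal protein genes (0.11) were higher. Transcription factors (-0.077), chemokines and homing receptors (-0.089), CREB/ATF partners (-0.10), interferon-stimulated genes (-0.12), cytotoxic effectors (-0.17), immediate-early genes (-0.24), macrophage and dendritic cell genes (-0.37), mature NK cell genes (-0.43) and B cell genes (-0.72) were lower. With an estimated correlation only mature NK cell genes kept the call (adjusted p = 0.0304), and the other 12 lists had adjusted p of 0.180 to 0.489. Ribosomal protein genes (0.150 and 0.239) and transcription factors (0.0653 and 0.0583) also lost it with quantile normalization and with scaling to the 75th percentile, and chemokines (0.0512) and CREB/ATF partners (0.0744) with quantile normalization. Of the 10 splits of the 6 arrays, the real one gave 14 probe sets and the highest other gave 1, and 10 splits are too few for a share under 0.05.

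Control probe sets, which the comparisons leave out, carried signal too. The 3 probe sets of Gapdh were higher in the 6 NKDxIL15tg than in the 3 IL15tg arrays, by 0.92 at the 3' end, 1.21 in the middle and 1.58 at the 5' end on the log2 scale. The bacterial controls LysX-3 and bioC-3 lay 1.35 and 1.60 above the highest other array in bone marrow replicate 3.

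In bone marrow replicate 3, 2080 probe sets lay over 2-fold above all 8 other arrays. Overall brightness of this array is argued against as the whole cause, since 67.8% of them still did so after quantile normalization. A fault of the measurement on this array may contribute. Of 45 bacterial control probe sets, which match no mouse RNA, 2 were raised in the same way, against 0 in any other array. They stood at 174.7 against at most 68.4, and at 141.7 against at most 46.6. As 7.70% of all tested probe sets were raised in this array, a larger share than 2 of 45, these controls cannot decide. Cells of another type in this sample cannot be told apart from such a fault. The 1682 other probe sets of the same genes, without those raised themselves, had a median difference of 0.073. Those of genes changed at least 2-fold between bone marrow and IL15tg spleen, without those called so themselves, followed with a median of 0.39. Leaving out the probe sets that moved holds both medians low, so they cannot decide. Among the 2080 raised probe sets, 10 were of the granulocyte and monocyte list. Its mean level was 10.11 in this array, against 5.86 to 9.34 in the others. The stem, mast cell and basophil list stood at 7.14, against 6.35 to 6.56. T cell genes (7.80, against at most 7.48) and neighbours of Atf2 (7.95, against at most 7.77) were also highest here. Some lists, such as B cell genes (6.63), were not. As lists of several kinds rose, these levels cannot part other cells from a fault. A difference between the mice also stays open and was not tested.

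Granulocyte and monocyte genes were higher as a list in both NKDxIL15tg groups, but not with an estimated correlation (adjusted p = 0.480 in spleen and 0.190 in bone marrow). The divergent bone marrow replicate 3 is argued against as the source, since without it the list's mean change in bone marrow against IL15tg spleen was 2.97. Granulocyte or monocyte precursors among the sorted NK cells cannot be told apart from other sources. Across the 20 genes of the list, fixed before the test, the rise in spleen and the rise in bone marrow over IL15tg spleen had a Spearman correlation of 0.958 (simulated unchanged groups with the shared IL15tg arrays: mean 0.455, 95th percentile 0.758), but 25.8% of 1000 draws of 20 other genes of like rise in bone marrow had one as high (median 0.934), and expression by the immature NK cells themselves predicts the same. The probe set of S100a8 stood at 148, 1806 and 5421 in IL15tg spleen, NKDxIL15tg spleen and NKDxIL15tg bone marrow, Csf1r was at a log2 level of 9.53 already in IL15tg spleen, and no gene of this list stands in another list. The sort for NK cells is meant to remove such cells, but no value here measures its purity or RNA released from other cells. Expression of these genes by immature NK cells themselves stays open and was not tested.

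A set of 50 genes outside the granulocyte and monocyte list was at least 8-fold higher in NKDxIL15tg than in IL15tg spleen. Its median intensity was 408 against 19.7. Genes of that list that rose as much, such as S100a8 and Camp, were left out of the set. Granulocyte precursors are argued against as the source of these 50 genes. Their median change from NKDxIL15tg spleen to bone marrow was -0.094 (-1.50 to 0.79), while the granulocyte list rose (mean 1.95, adjusted p = 0.180 in camera with an estimated correlation). The genes were picked by high values in NKDxIL15tg spleen, which are subtracted in this change, so the change is biased downward. With the listed genes left out, the argument holds for the 50 genes only. An effect of the transgene insertion reported at Atf2 on its neighbourhood is also argued against as the whole cause. On chromosome 2 lie 12% of the genes (6 of 50), against 8.02% of all tested genes (Fisher's exact test, 2-sided, p = 0.292). This share counts the whole chromosome and not the distance to Atf2, so it speaks only for the genes on other chromosomes. For the 6 genes on chromosome 2, among them Dlx1, Dlx2 and Dlx1as, such an effect stays open. The list of neighbours of the Atf2 locus did not hold these Dlx genes. Single faulty probe sets are argued against for the set by a share chosen after the result was seen. Of the 37 genes with another probe set, 25 (67.6%) had another one called higher without the filter, against 5.72% of all other genes with another probe set. All 66 other probe sets had a median change of 0.70, short of the bar set before the test. The 37 past the filter, which favours those that rose, had 2.15. For the remaining 25 genes, 13 without another probe set and 12 with none called higher, faulty probe sets cannot be told apart from a true rise. A difference in development between immature and mature NK cells, the one that the design names, stays open and was not tested. Other effects of the NKD genotype cannot be told apart from it.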

How the results depend on the processing

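Of the tests in this part, the replicate block without bone marrow replicate 3 was chosen after the data were seen, and all others were planned. No call became a call in the other direction in camera or for a probe set, but some values changed sign. The mean of the transcription factor list between the organs (-0.077) ranged from -0.166 to 0.032 with 1 array left out, with 0.004 without NKDxIL15tg spleen replicate 1 and 0.032 without bone marrow replicate 2. Second probe sets gave -0.14 for Rab27a (0.79) and -0.048 for Ndufb8 (0.63) between the spleens, and 0.31 for Bcl11b (-0.54), 0.11 for Prf1 (-0.87) and -0.90 for Tnfsf10 (0.19) between bone marrow and IL15tg spleen. For cytotoxic effectors, which camera did not call, fry called them higher between the spleens (mean 0.099) and between bone marrow and IL15tg spleen (mean -0.067), where camera pointed down. Over the alternatives, list results stayed on their side of the threshold 949 times, gained a call 39 times, lost one 88 times and changed sign with a call on one side 4 times, and named genes did so 2889, 19, 221 and 5 times. For NKDxIL15tg spleen against IL15tg spleen (3725), array weights gave 5685, 1 probe set per gene 1592 and a minimum of 2-fold 1249. The replicate block without bone marrow replicate 3 gave 6353 there and 31 for bone marrow against spleen of NKDxIL15tg mice (14), where no filter gave 2, a floor of 64 gave 4 and the replicate block 23. For NKDxIL15tg bone marrow against IL15tg spleen (5764), 1 probe set per gene gave 2588 and a minimum of 2-fold 1769. Array weights gave 4818 shared probe sets (3166). Testing fewer probe sets explains the counts with 1 per gene, and an added threshold those with 2-fold. For the others the cause was not tested. Leaving out 1 array gave 1809 (IL15tg replicate 1) to 5483 (bone marrow replicate 3) between the spleens, 1 (NKDxIL15tg spleen replicate 1) to 14 for bone marrow against spleen of NKDxIL15tg mice, 3089 (IL15tg replicate 1) to 6342 for bone marrow against IL15tg spleen and 1562 to 4340 shared, and fits without an array hold fewer samples. Between the spleens, bone marrow replicate 3 is in neither group and enters only through the shared spread, and a fit to the 6 arrays alone gave 5184. Why leaving it out raised the count between bone marrow and IL15tg spleen was not tested. The 14 probe sets were also called without bone marrow replicate 3. With quantile normalization the counts were 3328, 13 and 5709, and with scaling to the 75th percentile 3033, 19 and 5151; the share of higher probe sets in bone marrow against IL15tg spleen went from 45.9% to 36.3% and 37.9%. The replicate block changed the calls of 2 lists between the spleens and 1 between the organs, given there, and between bone marrow and IL15tg spleen gave 5957, with Tap1 (0.0639), Bcl11b (0.0527) and Cma1 (0.0638) lost and Kitl (0.00396), Col1a2 (0.0496) and Gzmb (0.0192) gained. Between the spleens it gained Kitl (0.0485). Signal over background limits what dim probe sets show: those below an intensity of 47.7 were not tested, and changes of genes near the floor of 16 in one group depend on the floor. Of the 10 splits of 6 arrays, the real one gave 3725 (spleens) and 5764 (bone marrow against IL15tg spleen), and the highest other gave 0 in both, and 10 splits are too few for a share under 0.05.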

Other observations

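No test in this part was added, and the genes named here were chosen after their values were seen. Among the 50 genes outside the granulocyte and monocyte list that were at least 8-fold higher in NKDxIL15tg than in IL15tg spleen, several were known from other tissues or from signalling. Both subunits of soluble guanylate cyclase, the receptor for nitric oxide, rose, Gucy1a1 by 3.52 ± 0.42 and Gucy1b1 by 3.85 ± 0.42. The homeobox neighbours Dlx1 and Dlx2 on chromosome 2 rose by 5.36 ± 0.17 and 4.61 ± 0.21, and the antisense transcript Dlx1as by 3.18 ± 0.16. Npy, which encodes neuropeptide Y, rose from 36.7 to 1030, and Tnfrsf11b, which encodes osteoprotegerin, by 4.72 ± 0.15. Trgv4, a variable segment of the T cell receptor gamma chain, rose by 3.98 ± 0.42, and Upp1, a uridine phosphorylase, by 4.15 ± 0.19. In bone marrow against IL15tg spleen the changes were 3.20 (Gucy1a1), 3.44 (Gucy1b1), 5.09 (Dlx1), 4.01 (Dlx2), 2.80 (Dlx1as), 5.06 (Npy), 4.49 (Tnfrsf11b) and 3.93 (Trgv4), and the lowest of the 50 genes was at 2.46.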
